A study of Bacillus subtilis subsp. subtilis str. 168 with 12 samples.

How the data were processed

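Gene expression of Bacillus subtilis was measured on 12 2-colour arrays in 2 comparisons. In the first, a strain labelled as lacking the 7 ECF (extracytoplasmic function) sigma factors and carrying sigV under a xylose-inducible promoter was set against itself, with xylose over without. In the second, wild type 168 with lysozyme was set against 168 without it. Per the labels' protocols, cells were grown in LB to an OD600 of 0.4, treated for 20 min and extracted with a column kit, and 20 microgram of total RNA went into each indirect cDNA labelling with Alexa Fluor 555 or 647. Per the series design, each comparison had 3 independent RNA preparations, and each preparation was hybridised on 2 arrays: a forward array with the treated sample in Alexa Fluor 647 and a dye-swapped array with it in Alexa Fluor 555.

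The authors' deposited table gives 1 log2 ratio per gene and array. The labels name the treated sample first on each array, and the table does not state the direction, scale or centring of the ratio. The scale was read as log2 and the direction as treated over untreated from the values, and whether arrays were centred stays unknown. The scanner, the background correction and any normalization are not given in the sources used here. The design fixed before the data were examined said that swapped arrays would be turned if the 2 arrays of a preparation correlated below 0. With xylose they did (r = -0.629, -0.519 and -0.354 across genes; -0.34, -0.06 and -0.214 without values at the floor described below), and with lysozyme r was -0.0533, 0.0286 and -0.0811. The swapped arrays were nevertheless left as deposited, which departs from that design. The reason is that 14 of the 15 genes of the sigV operon, the dlt operon and xylose utilisation lay above 0 on the mean of the swapped xylose arrays, as they did on the forward ones, although yrhM did so on swapped arrays by 0.03. The remaining gene, araE, was at the floor on all 6 arrays and counts for neither direction. The effect of turning the swapped arrays is given with the other alternatives.

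Many deposited folds are whole numbers or end in 0.5, as they would be if 1 dye channel were set to a floor of 1. Whether the authors set a floor, and how spots were averaged, is not given in the sources used here. A value was counted as at the floor when 2 times its fold was whole within the rounding of the 4 deposited decimals, when it was 0, or when its fold was over 3000, where 4 decimals cannot tell. That last part covered 9 xylose values, of sigV, xylB, xylA and yrhL, and 1 lysozyme value, of yrhM. For these the floor was assumed from the size of the fold and was not detected. On simulated values this rule found 100% of those at the floor and marked 0.14% of the others. The tolerance of the rule widens with the fold, and most of these other values had small folds. The 0.14% therefore does not hold for large folds, where more values above the floor would be marked. The size of a ratio at the floor is set by the brighter channel, so an order of genes that includes such values rests on it.

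The table has 4116 entries, of which 10 are control spots and were left out of every test; the other 4106 are genes. Of the gene names, 3036 match symbols of assembly ASM904v1 and 1070 do not. Many names on the array are older, but why names did not match was not tested. The file's names are kept, with the current name given where it is well known. The array's genome build is not given in the sources used here, so no coordinates are printed, and neighbouring genes were read from the order in that assembly.

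The forward and swapped array of a preparation were averaged, so n = 3 preparations per comparison. Missing values numbered 4 with xylose and 3 with lysozyme, and a gene was tested if each preparation had a value on at least 1 array. For each comparison limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) tested the mean log2 ratio against 0, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The difference between the 2 responses was tested in 1 limma fit over the 6 preparations. Every adjusted p printed for a gene comes from limma. Errors are standard deviations over the 3 preparations. Shifts of 24 gene lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The overlap of calls is given as a count, without the planned Fisher's exact test, since the construct sets the xylose call of the gene shared. Each list's genes were also adjusted over the list alone. The lists share members: all 5 dlt genes are in the SigX list and 10 peptidoglycan genes are in the SigM list.

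The lists and the rule for named genes belong to the same earlier design. The rule took up to 15 called genes with the largest rise and 10 with the largest fall and the same sign on all 6 arrays, all measured genes of the sigV operon, the dlt operon and xylose utilisation, the 7 ECF sigma factor genes, the 2 highest and 2 lowest genes of each other list, and up to 5 called genes per direction for the difference. Genes outside the rule are marked as chosen after their values were seen. The number of arrays limits the precision. In simulated data with the spread of each comparison, changes of 1, 2, 4 and 6 on the log2 scale in 50 genes each were recovered in 2%, 6%, 46% and 66% of cases for xylose and in 48%, 80%, 94% and 96% for lysozyme. For the difference the shares were 12%, 50%, 84% and 88%. More genes changed in the simulation than were called in the measured data, which loosens the Benjamini-Hochberg cutoff. These shares can therefore overstate what the measured data could detect. With lysozyme yrhM at 7.40 and dltB at 1.25 were not called (limma adjusted p = 0.276 for each). False calls were 2 of 62 calls for xylose, 17 of 176 for lysozyme and 18 of 135 for the difference (3.23%, 9.66% and 13.3%), so the last 2 exceeded the 5% aimed at. The simulation took each gene's SD over 3 preparations as its true spread. The recovered shares and the false calls describe that setting and may differ for the measured arrays. A simulated list of 28 independent genes shifted by 1 was called with the preset correlation (camera adjusted p = 1e-07 for xylose). With an estimated correlation its adjusted p was 0.919 for xylose and 0.116 for lysozyme. The preset test called 0 of 19 unchanged lists in each. Their genes were drawn independently too, so this count does not show how often the preset test calls unchanged lists of correlated genes.

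The alternatives were other scalings of the arrays, 1 dye orientation alone, all 6 arrays with the preparation as a random block with and without a dye term, both comparisons in 1 fit, a filter on missing values, a robust prior, a 2-fold minimum, other list tests (an estimated correlation, fry and camera on ranks), and leaving out each preparation. For the difference, whose main fit already held both comparisons, the setting with both comparisons in 1 fit added array weights. Where arrays were not averaged, where both comparisons shared 1 fit and with the robust prior, lists were tested with cameraPR on the moderated t. After the data were seen, 4 more were added: leaving out values at the floor, turning the swapped arrays, leaving out genes shared between lists, and weighting preparations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.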

Results

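The response of Bacillus subtilis to the sigma factor SigV was measured on 12 arrays in 2 comparisons. In the first, sigV was induced with xylose for 20 min in a strain that its label says lacks the 7 ECF sigma factors, which asks which genes follow SigV when its relatives are absent. Xylose itself and the induction of sigV go together in this comparison and cannot be told apart. In the second, wild-type cells were treated with lysozyme, an enzyme that cleaves the peptidoglycan of the cell wall. Each comparison had 3 RNA preparations, each hybridised in both dye orientations, and 4106 genes were tested in each. Ratios are treated over untreated on the log2 scale.

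The 2 sets of arrays differed in quality. At the floor lay 38.8% to 66.4% of the values on the xylose arrays and 2.58% to 27.3% on the lysozyme arrays. With xylose the mean log2 ratio of all genes was 1.70, 1.74 and 1.57 on the forward arrays of preparations 1 to 3 and -1.65, -1.73 and -2.66 on the swapped ones. The array medians were 0.56, 0.65 and 0 forward and -0.585, -0.74 and -2 swapped with xylose. With lysozyme they were 0, -0.01 and 0 forward and 0, 0.02 and 0.01 swapped. Without values at the floor the medians of the xylose arrays lay between -0.11 and 0.09. The tails still differed by dye: in preparation 1 the 5th and 95th percentiles were -1.21 and 2.94 forward and -3.15 and 1.18 swapped. For sigV, xylB, yrhL, yrhK, xynB and xynP only swapped xylose arrays were left, so their means without such values hold 1 dye orientation. Centring each array on its median would add 0.35 to every xylose mean, so the sign of xylose means between -0.35 and 0 rests on the scaling. On all 6 xylose arrays 1063 genes were at the floor, against 21 on all 6 lysozyme arrays. The median over all genes of the preparation means was -0.14 with xylose and 0.03 with lysozyme. The number of arrays limits the precision. The correlation across genes between preparations was 0.298, 0.16 and 0.0922 with xylose and 0.243, 0.216 and 0.42 with lysozyme.

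**Figure D1:**
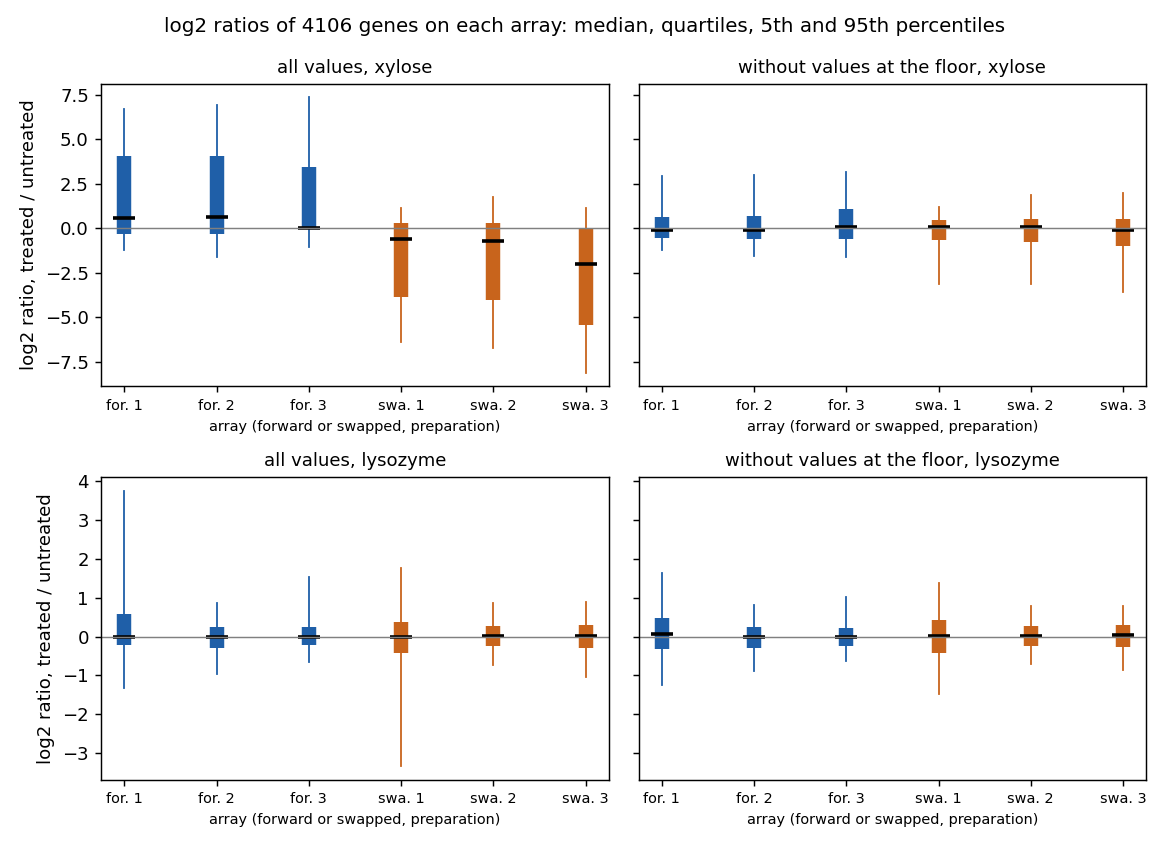
Log2 ratios of the 4106 genes on each array, treated over untreated, for xylose (top) and lysozyme (bottom), with all values (left) and without values at the floor (right). Black bars are medians, boxes the quartiles, lines the 5th to 95th percentiles, and blue and orange the forward and swapped arrays; with xylose the medians ran from -2 to 0.65 with all values and from -0.11 to 0.09 without those at the floor.

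The strain used for xylose was checked on the genes its label says it lacks. Of the 6 other ECF sigma factor genes, sigM, sigW, sigX, sigY and sigZ were at the floor on 6 of 6 xylose arrays, and ylaC (3.14 on forward and -2.85 on swapped arrays) was at the floor on 2 of 6. Values at the floor have no order, so no mean ratio is given for these 5. They can have 1 channel or both there, so they do not show that a gene gave no signal. The forward and swapped means were 1.98 and -2.39 for sigM, 4.06 and -5.14 for sigW and 3.38 and -3.55 for sigX. For sigY they were 2.76 and -3.48, and for sigZ 0.90 and -0.86. In wild type with lysozyme the same 5 genes were at the floor on 0, 0, 1, 1 and 2 of 6 arrays, and ylaC on 2 of 6. For ylaC the arrays therefore did not separate the strain from wild type. Which part of each gene was removed is not given in the sources used here, and 25.9% of all genes were at the floor on 6 of 6 xylose arrays.

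With xylose, sigV and xylB rose. The gene sigV, which the inducible promoter drives, had a mean log2 ratio of 10.89 ± 0.48 (SD, n = 3; adjusted p = 0.0213), and xylB, which encodes xylulokinase, had 11.15 ± 0.52 (adjusted p = 0.0213). Both lay above 0 on 6 of 6 arrays. The forward arrays of both genes were at the floor, and without them the means were 9.20 ± 1.14 for sigV and 8.98 ± 1.49 for xylB. These 2 were the only calls of limma, 2 up and 0 down. Unadjusted p was under 0.05 for 230 genes, where chance gives 205.3, and leaving out preparation 1, 2 or 3 left 0 calls of limma (198, 170 and 302 genes at an unadjusted p under 0.05). In these fits sigV had 10.95, 10.62 and 11.08 and xylB 11.12, 11.43 and 10.91. On forward arrays alone, and with the swapped arrays turned, limma called 0 genes (489 and 1299), and turned, sigV had 1.69 and xylB 2.17. Without values at the floor, a setting chosen after the data were seen, 7 of 1556 genes rose: sigV, xylB, xylR, yrhL, dltA, dltD and abh, each at adjusted p = 0.0438.

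The sigV operon holds sigV, its anti-sigma factor gene yrhM (rsiV), the peptidoglycan O-acetyltransferase gene yrhL (oatA) and yrhK. As a list it shifted up with xylose, with a mean of 7.08 ± 1.06 (SD, n = 3; camera adjusted p = 2.96e-11). The adjusted p was 0.29 with an estimated correlation. Adjusted over the list alone, 4 of 4 genes rose, and over all genes 1 did. The mean of the list was 4.66 on swapped arrays alone, where it was called. The mean was 7.68 ± 0.96 for yrhL, 6.80 ± 1.12 for yrhK (3 of 6 arrays at the floor each, and 5.09 ± 0.74 and 4.34 ± 1.53 without them) and 2.97 ± 2.16 for yrhM, which had 4 of 6 arrays at the floor and lay above 0 on 5. For yrhM the mean was 5.92 on forward and 0.03 on swapped arrays, and 1.80 ± 0.76 over the 2 arrays not at the floor.

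The dlt operon, whose products add D-alanine to teichoic acids, shifted up with xylose by 4.59 ± 1.34 (n = 3; camera adjusted p = 6.79e-11, adjusted p = 0.378 with an estimated correlation). All 5 genes, dltA to dltE, lay above 0 on 6 of 6 arrays and rose when adjusted over the list alone, with 0 called over all genes. The direction of the swapped arrays was chosen partly on these genes, with those of the sigV operon and xylose utilisation. Their shared sign on forward and swapped xylose arrays is therefore not independent support for a rise. The mean was 2.97 ± 0.14 for dltA, which had no array at the floor, and 5.50 ± 1.65 for dltB, which had 2 of 6 at the floor. The other 3 had 1 array each there. With such values left out dltB had 4.03 ± 0.62 and dltD 4.04 ± 0.21. The mean of the 5 genes was 8.51 on the forward array of preparation 3 and 3.49 to 4.31 on the others. With the swapped arrays turned, the dlt mean was 0.86 and neither it nor the lists of the sigV operon and xylose utilisation were called (adjusted p = 0.687, 0.0831 and 0.236). The xylose utilisation genes shifted up by 6.38 ± 0.69 (camera adjusted p = 8.54e-12, adjusted p = 0.285 with an estimated correlation), and on swapped arrays alone their mean was 4.15. Over the list alone 5 of 6 rose, and 1 did over all genes: the mean was 8.59 ± 0.93 for xylA (xylose isomerase), 7.16 ± 0.75 for xynB (beta-xylosidase), 7.02 ± 1.08 for xynP and 5.07 ± 2.27 for the repressor gene xylR, with 2, 3, 3 and 1 of 6 arrays at the floor. With values at the floor left out they had 6.34 ± 1.08, 4.06 ± 1.31, 5.02 ± 1.49 and 3.90 ± 0.28. The sixth, the transporter gene araE, was at the floor on all 6 arrays, so no ratio is given.

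**Figure D2:**
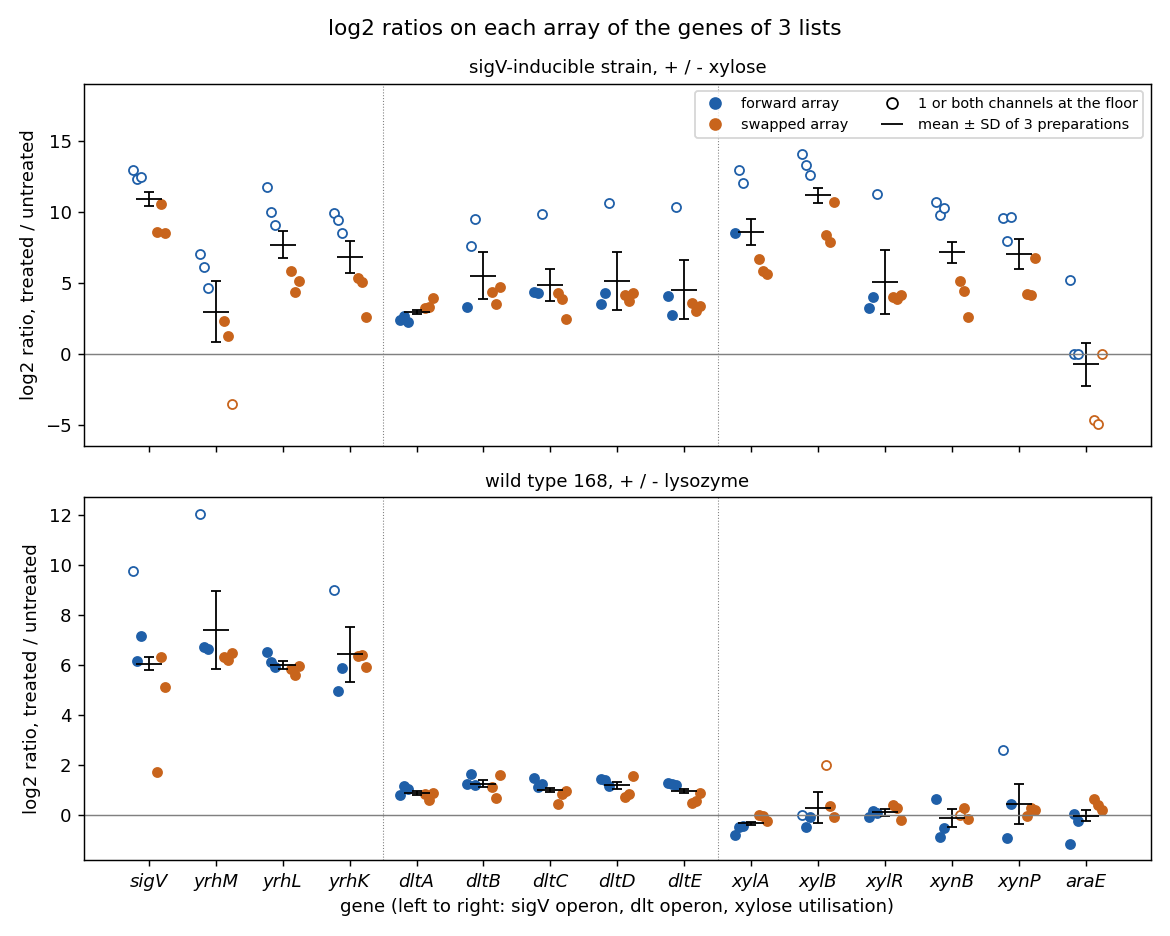
Log2 ratio, treated over untreated, of the genes of the sigV operon, the dlt operon and xylose utilisation on each array, for xylose (top) and lysozyme (bottom). Blue and orange points are forward and swapped arrays, and bars are the mean ± SD of the 3 preparations. Open points were counted as having a channel at the floor, some of them for their size alone. With xylose sigV had 10.89 ± 0.48 and dltA 2.97 ± 0.14. With lysozyme yrhL had 5.99 ± 0.17 and dltA 0.88 ± 0.07.

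Of the other lists, those of the related sigma factors shifted up with xylose. The SigM list (cell wall synthesis and division) had a mean of 1.26 ± 0.29, the SigX list (cell surface modification) 1.94 ± 0.13 and the SigW list (antibiotic resistance and membrane) 0.38 ± 0.50 (camera adjusted p = 3.76e-09, 9.5e-06 and 0.00131). With an estimated correlation the adjusted p was 0.285, 0.29 and 0.399. Over the list alone 4 of 39 SigM genes rose, 6 of 16 SigX genes and 0 of 53 SigW genes, with 0 called over all genes. Of the SigM list, ywoA (bcrC, which recycles the lipid carrier of cell wall synthesis) had 5.94 ± 2.23 (4 of 6 arrays at the floor) and the regulator gene abh 5.62 ± 2.10 (1 of 6). The lowest means were those of yacK (-1.19 ± 2.30, 1 of 6, and 0.17 without it) and lytR (-1.17 ± 1.91, 2 of 6). The SigM mean was 2.97 on forward and -0.46 on swapped arrays, and 0.65 over the 15 genes left without values at the floor. The SigX mean was 3.46 on forward and 0.42 on swapped arrays, and the SigW mean 2.44 and -1.69. The SigW list had preparation means of 0.73, 0.59 and -0.19, and a mean of 0.20 without preparation 1 and 0.66 without preparation 3, and was called in both. Without the genes it shares with other lists, an alternative chosen after the data were seen, the SigX list had a mean of -0.13 and was not called (adjusted p = 0.939). The SigM list was not called on forward arrays alone, nor were the SigX and SigW lists (adjusted p = 0.1, 0.119 and 0.0898). The SigW list was not called either on swapped arrays alone or without values at the floor (adjusted p = 0.444 and 0.0655).

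The last 3 called lists were lost when 1 preparation was left out. The SigB list (general stress) shifted up with xylose by 0.62 ± 1.48 (n = 3; camera adjusted p = 7.24e-08), with preparation means of 0.44, 2.17 and -0.77, and its mean was -0.16 without preparation 2 and 1.31 without preparation 3. The pyrimidine synthesis list shifted down by -1.83 ± 1.87 (camera adjusted p = 0.000327), with preparation means of -0.60, -3.98 and -0.90. Carbon catabolite repression targets shifted down by -0.71 ± 0.61 (camera adjusted p = 0.0226). The adjusted p was 0.644 for each of the 3 with an estimated correlation. Without preparation 2 none of the 3 was called (adjusted p = 0.392, 0.0823 and 0.106), and the carbon list was not called without preparation 3 either (adjusted p = 0.0809). With values at the floor left out the mean was -1.15 for the pyrimidine list and -0.39 for the carbon list, and without preparation 3 the latter was -0.40. On forward arrays alone the direction of the SigB list was down (adjusted p = 0.792), and on swapped arrays alone the pyrimidine and carbon lists were not called (adjusted p = 0.417 and 0.306). The means on forward and swapped arrays were 1.63 and -0.40 for SigB, -0.99 and -2.66 for pyrimidine synthesis and 1.25 and -2.68 for the carbon list. No gene of these lists passed the test over the list alone: pyrC had -2.94 ± 1.94, ydaD 1.77 ± 4.60 and dctP, a dicarboxylate transporter gene, -3.88 ± 2.96, with 2, 2 and 1 of 6 arrays at the floor (ydaD had 2.66 without them).

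The remaining 15 lists were not called with xylose. Their means were 0.51 for peptidoglycan synthesis (camera adjusted p = 0.0539), 0.16 for heat shock, -0.02 for biofilm matrix, -0.10 for iron homeostasis, -0.11 for purine synthesis, -0.13 for motility, -0.14 for the SOS response and -0.16 for ribosomal proteins. The other means were -0.20 for WalRK and cell wall hydrolases, -0.21 for teichoic acid synthesis, -0.25 for the PBSX prophage, -0.29 for competence, -0.47 for antimicrobial peptide transporters, -0.64 for CssRS secretion stress and -0.68 for the Lia operon. With values at the floor left out, ribosomal proteins were called down (mean -0.14, adjusted p = 0.00791) and heat shock up (0.21, adjusted p = 0.0458), and the means had the other sign for peptidoglycan (-0.07), iron (0.22), teichoic acid (0.26), WalRK (0.01), and, over 3 genes, competence (0.20). The Lia, antimicrobial peptide and biofilm lists had 1 gene left and were not tested. Without preparation 2 peptidoglycan synthesis (0.54, adjusted p = 0.035) and heat shock (0.24, adjusted p = 0.0332) were called up, and without preparation 3 ribosomal proteins down (-0.19, adjusted p = 0.0391). Centred, peptidoglycan synthesis had 0.86 and was called (adjusted p = 0.0315). Camera compares a list with the other genes: its direction was up in WalRK, motility, SOS and biofilm, where mean and median lay below 0, and in iron, where only the median lay above 0.

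With lysozyme yrhL and sigV rose in wild type. The gene yrhL had a mean log2 ratio of 5.99 ± 0.17 (SD, n = 3; adjusted p = 0.0196) with no array at the floor, and sigV had 6.04 ± 0.26 (adjusted p = 0.0223) with 1 array at the floor. Both lay above 0 on 6 of 6 arrays. These were the 2 calls of limma, 2 up and 0 down, with 462 genes at an unadjusted p under 0.05, where chance gives 205.3. The sigV values of preparation 1 were 9.76 and 1.73 on its 2 arrays, with a mean of 5.75, near the other preparations. The SD and the limma test of sigV use preparation means only, so its SD understates the spread between arrays. Without values at the floor sigV had 4.70 ± 2.58 and was not called (adjusted p = 0.271). The mean of the sigV operon on the forward array of preparation 1 was 9.33, and 5.07 to 6.40 on the others. With values at the floor left out, 4 of 3317 genes rose: yrhM (6.45 ± 0.11, adjusted p = 0.00235), yrhL (adjusted p = 0.00277), yrhK (5.98 ± 0.36, adjusted p = 0.0107) and ywoA (1.86 ± 0.10, adjusted p = 0.0487). The yrhM value left out, 12.04 on the forward array of preparation 1, was counted as at the floor for its size alone. With it yrhM had 7.40 ± 1.55 and was not called (limma adjusted p = 0.276), so the yrhM call rests on leaving out this high value. Leaving out preparation 2 or 3 left 0 calls of limma (183 and 181 genes at an unadjusted p under 0.05), and leaving out preparation 1 gave 4. Forward arrays alone and turned swapped arrays also gave 0 (301 and 175). Without preparation 2 or 3 sigV had 5.94 and 6.00 and yrhL 6.06 and 6.01. On forward arrays alone they had 7.69 and 6.18. Turned, sigV had 1.65 and yrhL 0.19. After quantile normalisation sigV had 5.92 and on swapped arrays alone 4.39, and was not called (adjusted p = 0.265 and 0.55).

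As a list the sigV operon shifted up with lysozyme by 6.46 ± 0.64 (camera adjusted p = 3.72e-08, adjusted p = 0.22 with an estimated correlation), and adjusted over the list alone 4 of 4 genes rose. With values at the floor included, yrhM had 7.40 ± 1.55 and yrhK 6.42 ± 1.10. The dlt operon shifted up by 1.06 ± 0.10 (camera adjusted p = 2.55e-07, adjusted p = 0.48 with an estimated correlation). All 5 genes lay above 0 on 6 of 6 arrays with no array at the floor and rose when adjusted over the list alone, from 0.88 ± 0.07 for dltA to 1.25 ± 0.15 for dltB. None of them was called over all genes. The xylose utilisation genes had a mean of 0.06 ± 0.25 and 0 of 6 passed the test over the list alone. With the swapped arrays turned, 0 lists were called with lysozyme. Of the other ECF sigma factor genes, sigM had 0.39 ± 0.08 and lay above 0 on 6 of 6 arrays, sigW 0.19 ± 0.11, sigX 0.10 ± 0.12, sigY 0.88 ± 2.08 (0.19 without values at the floor), sigZ -0.18 ± 0.34 and ylaC -0.48 ± 0.28, none called over all genes. The mean of ylaC joins -2.89 on forward and 1.92 on swapped arrays, with 2 of 6 arrays at the floor, so its SD understates the spread.

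The SigM list shifted up with lysozyme by 0.72 ± 0.10 (n = 3; camera adjusted p = 2.41e-14), with preparation means of 0.62, 0.72 and 0.81. The adjusted p was 0.22 with an estimated correlation. Adjusted over the list alone 17 of 39 genes rose, 0 fell and 22 did not pass, and over all genes 0 were called. Among those that rose, chosen after their values were seen, were ddl (D-alanine ligase, 1.14 ± 0.07), murF (peptidoglycan precursor synthesis, 0.82 ± 0.06), mreC (cell shape, 0.81 ± 0.08) and maf (septum formation, 1.30 ± 0.10), each above 0 on 6 of 6 arrays. The highest means of the list were those of ycgR (2.25 ± 1.84, 1 of 6 arrays at the floor, and 1.37 without it) and ycgQ (1.91 ± 1.73, 2 of 6). The lowest were those of yacL (-1.64 ± 2.82, 1 of 6, and -0.27 without it) and radA (-0.36 ± 0.91, none), and none of the 4 passed. The SigX list shifted up by 0.57 ± 0.09 (camera adjusted p = 0.000241, adjusted p = 0.305 with an estimated correlation). Its 5 genes that rose over the list alone were the dlt genes, and without shared genes, an alternative chosen after the data were seen, the list was not called (adjusted p = 0.866). Peptidoglycan synthesis shifted up by 0.36 ± 0.09 (camera adjusted p = 0.000102, adjusted p = 0.305 with an estimated correlation), with 3 of 38 genes up over the list alone, ywoA, ddl and murF, all shared with the SigM list. Without shared genes it was not called either (adjusted p = 0.105).

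The SigB list shifted down with lysozyme by -0.47 ± 0.07 (n = 3; camera adjusted p = 7.12e-12, adjusted p = 0.22 with an estimated correlation). Its preparation means were -0.50, -0.52 and -0.39. Adjusted over the list alone 15 of 61 genes fell and 0 rose, with 0 called over all genes. Those that fell, chosen after their values were seen, include the general stress gene gspA (-1.01 ± 0.28, below 0 on 6 of 6 arrays), the anti-sigma factor gene rsbW (-0.72 ± 0.11, 6 of 6) and csbC (-1.14 ± 0.20, 5 of 6). The lowest means of the list were those of yflT (-2.43 ± 2.54, 2 of 6 arrays at the floor) and ycdF (-2.07 ± 2.06, 1 of 6). The highest were those of ywmF (0.86 ± 0.75, 5 of 6) and yfhF (0.50 ± 1.40, 1 of 6, and -0.17 without it), and none of the 4 passed. Motility and chemotaxis shifted down by -0.22 ± 0.05 (camera adjusted p = 1.35e-09, adjusted p = 0.48 with an estimated correlation). Of its 51 genes 47 lay below 0, and 0 passed over the list alone.

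Iron homeostasis shifted up with lysozyme by 0.66 ± 0.56 (camera adjusted p = 9.15e-07, adjusted p = 0.764 with an estimated correlation), with preparation means of 1.21, 0.69 and 0.09 and a mean of 0.39 without preparation 1. Purine synthesis shifted up by 0.20 ± 0.17 (camera adjusted p = 0.0204) and pyrimidine synthesis down by -0.39 ± 0.34 (camera adjusted p = 0.000904). The preparation means of the latter were -0.68, -0.46 and -0.02, and without preparation 1 it had -0.24 and was called. Purine and pyrimidine synthesis had an adjusted p of 0.764 with an estimated correlation, and no gene of the 3 lists passed over the list alone. The purine list was not called without preparation 3 (mean 0.15, adjusted p = 0.498), on swapped arrays alone (adjusted p = 0.193), with the preparation as a random block (adjusted p = 0.0739) or with a robust prior (adjusted p = 0.131). The pyrimidine list was not called on swapped arrays alone (adjusted p = 0.062) or with both comparisons in 1 fit (adjusted p = 0.157, and 0.262 for purine).

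The cell wall hydrolase list was not called with lysozyme (mean -0.00043 ± 0.02, camera adjusted p = 0.773). Over the list alone the hydrolase gene lytE rose (0.86 ± 0.27), and yocH (-0.71 ± 0.08), lytB (-0.71 ± 0.03) and lytA (-0.65 ± 0.20) fell; lytA was chosen after its value was seen. The other lists not called had means of 0.12 for SigW (0.13 without preparation 1, where it was called, adjusted p = 0.0132), 0.18 for the Lia operon, 0.0040 for antimicrobial peptide transporters, 0.03 for CssRS, 0.06 for teichoic acid synthesis, 0.02 for competence, -0.12 for biofilm matrix, -0.01 for ribosomal proteins, -0.02 for heat shock, 0.04 for SOS, 0.04 for PBSX and 0.03 for carbon catabolite repression targets. In the competence and xylose utilisation lists mean and median were above 0 and camera's direction was down. The mean was above 0 and the median below it in CssRS (direction down) and the antimicrobial peptide transporters (direction up), and the reverse held for ribosomal proteins (direction down).

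**Figure D3:**
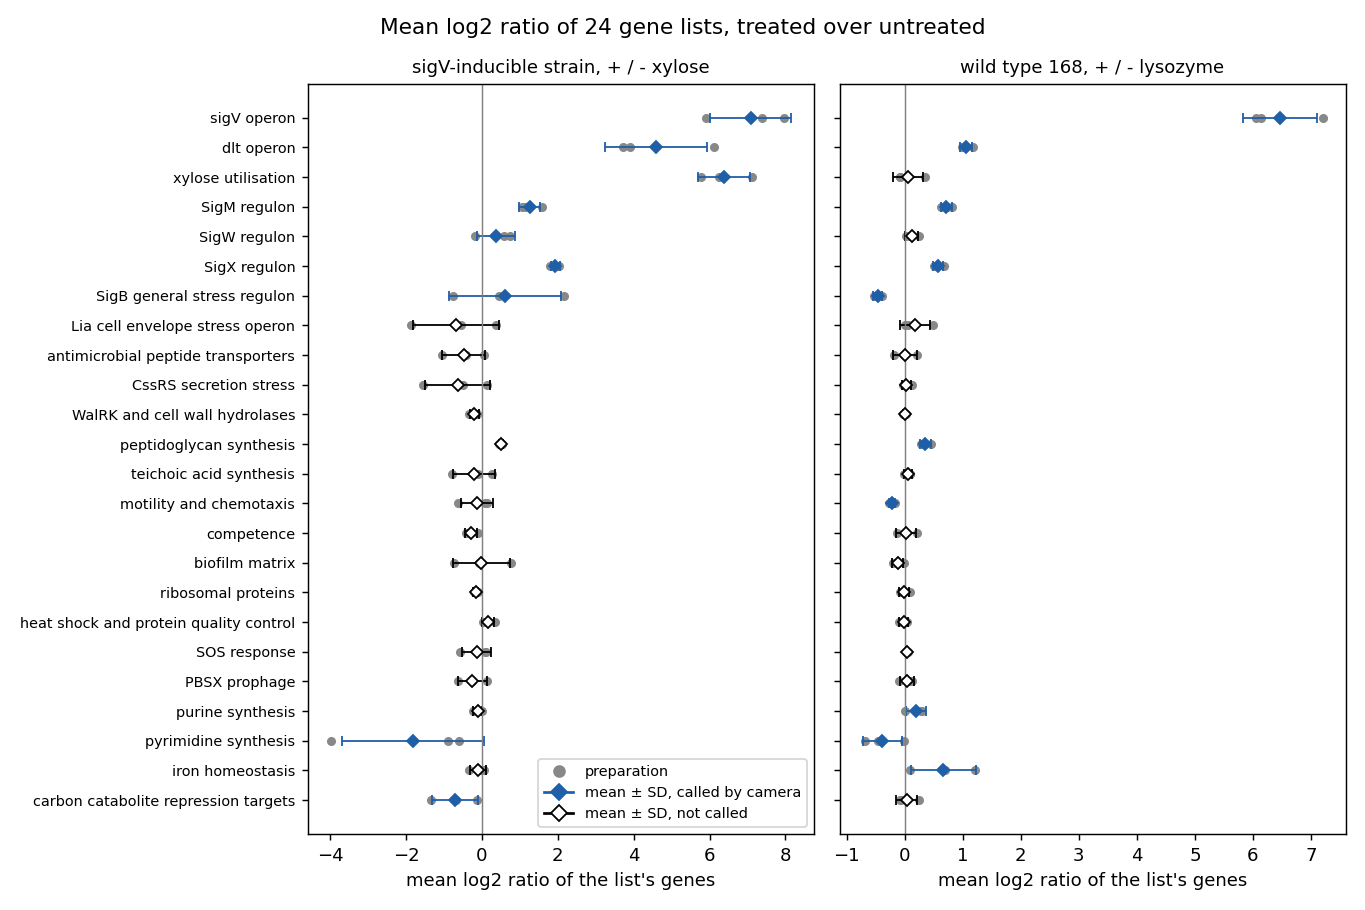
Mean log2 ratio, treated over untreated, of the measured genes of 24 lists with xylose (left) and lysozyme (right), on axes of different range. Grey points are the 3 preparations, diamonds and bars their mean ± SD, and blue diamonds the lists called by camera with the preset correlation; the SigB list had 0.62 ± 1.48 with xylose and -0.47 ± 0.07 with lysozyme.

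The 2 responses were then compared. Strain and treatment both differ between the comparisons, so no difference can be assigned to either. Xylose was given in only 1 of them, and there the inducible promoter drives sigV. Differences in sigV and the xylose utilisation genes can therefore come from the design itself. Of the 4106 genes, 4 differed, all lower with lysozyme than with xylose: xylB (difference -10.87, adjusted p = 0.00202), xylA (-8.93, adjusted p = 0.00546), xynB (-7.26, adjusted p = 0.00788) and sigV (-4.84, adjusted p = 0.0163). The means of sigV behind this were 6.04 with lysozyme and 10.89 with xylose. No gene differed the other way in this fit, and 357 genes had an unadjusted p under 0.05, where chance gives 205.3. Other settings gave both directions: higher with lysozyme were 6 of 197 genes on forward arrays alone, 626 of 657 on swapped arrays alone, 9 of 21 with the random block, 8 of 17 with a dye term and 5 of 14 with array weights. The difference of sigV was -1.16 after quantile normalisation (adjusted p = 0.586), and with swapped arrays turned that of sigV was -0.04, of xylB -2.64 and of xylA -2.80, none called. Of the dlt genes dltA had the lowest adjusted p (difference -2.08, adjusted p = 0.174). Without values at the floor 10 of 1461 genes differed, 7 lower with lysozyme (xylA, xylR, abh, dltA, dltB, dltD and dltE) and 3 higher. Of the 4 genes above, sigV had -4.49 there (adjusted p = 0.36) and xynB -4.06 (adjusted p = 0.0807), and neither was called, and xylB could not be tested. The 3 that were higher, chosen after their values were seen, were kipA (1.72), yngL (1.67) and yxiJ (1.58). The count was 40 without xylose preparation 3 (15 higher with lysozyme), 3 without xylose preparation 1 and 2 without xylose preparation 2. It was 1 without any single lysozyme preparation.

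In both comparisons 1 gene was called, sigV, up in each. With xylose the inducible promoter drives sigV, so this overlap does not show a shared response. It was 0 in 5 of the 6 fits without 1 preparation. No gene was called down in either. Across the 4106 genes, which are not independent replicates, the 2 responses had a Pearson correlation of 0.123 and a Spearman correlation of -0.00239. Without values at the floor these were 0.232 and 0.0210 over 1461 genes.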

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

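The tests of explanations in this part were chosen after the results were seen; the search for arrays far from the others and the counts over other splits were planned. Over the 60 quantities tested per array, 5 had an array far from the other 5, where chance gives about 3 (1 in 20). With xylose the mean of the dlt genes on the forward array of preparation 3 was 8.51, against 3.49 to 4.31 on the others. The mean of the motility genes on the swapped array of preparation 3 was -1.78, against -0.24 to 0.54. With lysozyme the forward array of preparation 1 stood apart in the sigV operon (9.33, against 5.07 to 6.40), the Lia operon (1.16, against -0.22 to 0.22) and the competence list (0.73, against -0.31 to 0.07). These arrays had 64.9%, 66.4% and 27.3% of their values at the floor.

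Of the 10 control spots, which no comparison uses, 2 had opposite signs in the 2 dye orientations on every xylose array. BMV-RNA3 had a mean of 4.11 on the forward arrays and -5.47 on the swapped ones, and Ecoli-yjcG had 2.66 and -3.13. Both were above 0 on 3 of 3 forward arrays and below 0 on 3 of 3 swapped arrays, and 7 of the 10 spots changed sign between the means of the 2 orientations. The other 3 had a forward mean of 0 and swapped means of 0, -0.33 and -1.11.

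The whole set of xylose arrays showed the same opposite shift, and 2 technical explanations were weighed. Of the values with 1 channel at the floor, 93.8% had the Alexa Fluor 555 channel there, so a weak 555 signal is 1 candidate cause. If swapped arrays had been left as untreated over treated, genes that rise with xylose would lie below 0 on them. The gene sigV, which the inducible promoter drives, had a mean of 9.20 on them, which argues against this. Of the 15 genes of the sigV operon, the dlt operon and xylose utilisation, 14 had a mean above 0, yrhM by only 0.03. That count is no separate test, since the rise of the dlt genes is itself a result and these genes were used to choose the direction. The share at 555 rests on that direction, and with swapped arrays turned it would be 45.5%. No biological explanation was tested, since treatment and dye are exchanged within each preparation.

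The SigB and pyrimidine lists were shifted most in xylose preparation 2, and a dye or floor artefact was weighed against a change common to the treated cultures. The orientation of preparation 2 nearer to 0, without values at the floor, still had a mean of 1.57 for SigB and -3.50 for pyrimidine synthesis, which argues against dye and floor. The SigB mean in preparation 3 was -0.23 ± 0.15 (SE over 49 genes), past the limit set against a change common to all 3 cultures. That SE over genes of 1 preparation holds no spread between cultures. The arrays of preparation 3 also had 64.9% and 66.4% of their values at the floor, so a common change stays open. For the pyrimidine list preparation 3 had 0.59 ± 0.72 (SE over 6 genes). The test was widened by 2 standard errors after this value was seen, and a common change stays open there too. A difference between the 2 cultures of preparation 2 unrelated to xylose may account for both shifts and was not tested.

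Turning the sign of 1 preparation gives 4 splits per comparison, too few for a share under 0.05. With xylose 1 split, the real one, gave the 2 calls, and the highest other gave 0; with lysozyme the same was found. For the difference the real split gave 4 calls and the highest of the other 9 splits gave 0, and 10 splits are also too few.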

How the results depend on the processing

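The settings on values at the floor, turned swapped arrays, shared genes and weights of preparations were chosen after the data were seen. The others, array weights for the difference included, were chosen before. Unless a sentence says otherwise, the cause of a change was not tested. Under every setting but turning, the list of the sigV operon and that of the dlt operon kept its call in both comparisons, except with an estimated correlation and, for dlt with xylose, with fry; without shared genes the dlt list has no genes left to test.

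Genes called with xylose were 2, and the count was 8 after centring each array, 0 on forward arrays alone, 478 on swapped arrays alone (13 up, 465 down), 12 with all arrays and the preparation as random block (10 up, 2 down), 8 with a dye term added, 27 with both comparisons in 1 fit (15 up, 12 down), 7 without values at the floor (1556 genes tested), 7 with weights and 0 with swapped arrays turned. Both genes were among those called in each of these but the settings with 0. At an unadjusted p under 0.05 the 0 counts had 489 genes (forward) and 1299 (turned). Without 1 preparation the count was 0 to 0. Genes called with lysozyme were 2, and 0 on forward arrays alone (301 at unadjusted p under 0.05), 60 with the random block (33 up, 27 down), 22 with a dye term (19 up, 3 down), 4 without values at the floor and 0 with swapped arrays turned (175), and 0 to 4 without 1 preparation.

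Genes that differed between the responses were 4, all lower with lysozyme. The count was 197 on forward arrays (6 higher, 191 lower), 657 on swapped arrays (626 higher, 31 lower), 21 with the random block (9 and 12), 17 with a dye term (8 and 9), 14 with array weights (5 and 9), 10 without values at the floor (3 and 7), 633 with swapped arrays turned (27 and 606), and 1 to 40 without 1 preparation. With the replicate number as a block 0 genes were called (306 at unadjusted p under 0.05). Deviations of same-numbered preparations correlated at 0.0381, -0.0238 and -0.00571, and not every preparation correlated best with its own number, so the numbers do not pair the samples. Genes called in both comparisons were 1, and 2 after centring, 0 after quantile normalisation, 0 on forward arrays, 6 with the random block, 4 with a dye term, 3 with both comparisons in 1 fit, 0 with swapped arrays turned, and 0 to 1 without 1 preparation. The correlation of the responses was 0.123, and 0.0595 on swapped arrays, 0.232 without values at the floor, 0.0546 with swapped arrays turned, and 0.0881 to 0.146 without 1 preparation.

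Lists called were 9 with xylose and 10 with lysozyme. With an estimated correlation they were 0 and 0, with fry 3 and 6, and without 1 preparation 8 to 9 and 9 to 11. With swapped arrays turned they were 9 (2 up, 7 down, 1 of them among the 9 reported) and 0. With xylose they were 13 on forward arrays alone (5 up, 8 down, 5 among the 9) and 13 on swapped arrays alone (11 up, 2 down, 6 among the 9). Counted as turned are list tests that were called, as reported or under the setting, and had opposite directions in the 2. With xylose on forward arrays alone they were SigB (mean 1.63), antimicrobial peptide transporters (3.12), motility (0.16), heat shock (0.44) and iron homeostasis (0.22). On swapped xylose arrays alone they were biofilm matrix (-4.00), ribosomal proteins (0.41) and the PBSX prophage (-0.71). With swapped arrays turned they were dlt (0.86), SigM (1.72), SigX (1.52), SigB (1.01), antimicrobial peptide transporters (3.59), motility (0.29), heat shock (0.28) and iron homeostasis (0.32) with xylose and SigM (-0.0288) with lysozyme. Direction is relative to the other genes, so it can oppose the mean. Of 859 list values under the alternatives 684 kept their direction and side of the threshold and 17 turned in that sense. Of 2888 values of named genes 2423 were counted as the same. A gene called in either setting had to keep its call and sign for this. An uncalled gene had to move by less than its SD over preparations, with no check of its sign. Of the called values 0 changed sign. Values at the floor made up 38.8% to 66.4% of each xylose array.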

Other observations

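The tests and the genes named in this part were chosen after the values were seen. Next to the sigV operon, yrhI had a mean log2 ratio of 1.58 ± 0.21 (SD, n = 3) with lysozyme, above 0 on 6 of 6 arrays with no array at the floor, and was not called over all genes (limma adjusted p = 0.276). With xylose yrhI had 4.94 ± 2.84 and yrhJ 4.83 ± 3.15, each with 4 of 6 arrays at the floor. Both lie after yrhK, with yrhJ the nearer, if they are the genes now named bscR and cypB, which is background knowledge. On the other side of sigV, yrhO had 0.14 ± 0.08 and yrhP -0.38 ± 0.85 with lysozyme, and yrhH, beyond yrhI, had -0.07 ± 0.26.

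A hypothesis is that transcription runs past yrhK into yrhJ and yrhI with lysozyme, in which case yrhJ should lie near yrhI or above it. The strands of these genes were not considered, and the prediction may not hold if they are read against yrhK. With all values yrhJ had 1.86 ± 2.40 (1 array at the floor), above yrhI, and without the value at the floor 0.16 ± 0.62, which is -1.41 relative to yrhI, so the order of the 2 rests on 1 array. The genes on the other side of sigV lay under yrhI, as the hypothesis needs. A high level of yrhJ from another promoter could hide such transcripts in its ratio, although with xylose, in the other strain, that ratio was 4.02 over the 2 arrays not at the floor and was not called. The level of yrhJ in wild type was not measured apart from its ratio, and the question stays open for lysozyme.

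A further hypothesis is that the SigM-list genes that respond to lysozyme are those that respond to xylose in the sigV-inducible strain. That response holds the effects of xylose itself and of SigV together. Across the 15 of 39 genes with values above the floor in all preparations, the Spearman correlation of the 2 responses was 0.468 (permutation p = 0.0799, two-sided, 100000 permutations), and Pearson's r was 0.261. Genes are not independent replicates. Over all 39 genes, with values at the floor, the Spearman correlation was 0.651. The test did not pass at 0.05, so these arrays leave the hypothesis open.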
